A study of Streptomyces tsukubensis NRRL18488 with 16 samples.

How the data were processed

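The arrays hold cDNA of total RNA labelled with Cy3 from random hexamers, hybridized together with genomic DNA labelled with Cy5, the same reference on all arrays, per the labels' protocols. The strain was grown in 0.5 L flasks with 100 mL of the medium MGm-2.5 at 28 °C and 220 rpm, per the labels. The deposited scanner files give the intensity of each spot and of its local background in both channels, read with Agilent Feature Extraction 9.5.1.1, per the file headers. They also hold the intensity that this software had corrected for background and dye, per the file headers, which served only as an alternative. A deposited value table of the same arrays holds log2 ratios processed by the authors, for which the submitters' processing notes name limma 3.20. Which steps they ran is not given in the sources used here. Set against the scanner values, its columns correlated at r = 0.99 with log2(Cy3/Cy5) and had slopes between 0.90 and 1.11, so the direction and the log2 scale are known, while its exact scaling and centring stay unknown. Its column medians lay between -0.22 and -0.0013, in the order of the 4 times -0.22, -0.15, -0.05 and -0.10 for NAG replicate 1, -0.15, -0.02, -0.0013 and -0.13 for NAG replicate 2, -0.13, -0.08, -0.05 and -0.19 for CTL replicate 1 and -0.09, -0.11, -0.13 and -0.09 for CTL replicate 2. It served as an alternative, and the named IDs are not analysed in it.

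Of 15744 spots, 15208 were no controls and held 14808 distinct probes, 4255 of them in tilings. Control spots and outlier spots were left out. Intensities were corrected with normexp (offset 50) in R 4.3.3 with limma 3.58.1, log2(Cy3/Cy5) was taken, and the ratios were brought to the same quantiles on all arrays, with no loess, since the ratio to genomic DNA follows the level of a transcript. Probes of an ID were averaged, and 9531 of 9534 IDs were kept, which had a probe well above background in Cy3 on both arrays of at least 1 group. Every spot of the named IDs was well above background on all arrays and none was saturated. Of 20 named IDs with more than 1 probe, 3 had probes with changes of opposite sign (SCO1712, SCO6008 and the ID in fkb ORF 1).

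Groups, replicates and times come from the sample labels, which number 4 cultures. All comparisons came from 1 limma fit of 8 group means over the 16 arrays, with the culture as a random block (consensus correlation 0.242), empirical Bayes moderation and Benjamini-Hochberg adjustment, at a threshold of 0.05. These designs, the alternatives and the gene lists were fixed before the data were examined, except where the text names a later choice. The tested results are the change from 70 h in NAG minus that in CTL at each time and averaged, NAG against CTL at each time, and a moderated F test over the times in each medium. SEs are those of the fit. Replicate numbers mark the slide, and each of the 2 slides held both media. The correlation of the deviations of same-numbered NAG and CTL arrays from their group means was 0.38, -0.15, 0.19 and 0.02 at 70, 70.5, 71 and 72 h, so the numbers were not taken to pair the samples.

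None of the 9534 IDs matched the gene table of the reference by name, and names come from the 16 tiled regions of the array. Tiled probes were joined by overlaps of at least 6 nt, with gaps of unknown length drawn as 30 nt, and ORFs were called with prodigal 2.6.3. IDs were assigned to a region where at least 1 of their probes lay in its tiling, and all probes of an ID were averaged. For the IDs with 1 of 2 probes placed, the averaged change of the separate probes was -0.31 and -0.28 for dasR, -1.49 and -0.88 for pfkA2, 1.23 and 1.49 for pfkA3, -1.62 and -1.44 for wblA and -0.98 and -0.73 for the lower rshA ID. The mean of the probes of each strand of an ORF, or of a region with no whole ORF, was a feature of its own, and 98 such features were adjusted apart from the IDs. Genes were named by a rule: among IDs past the threshold with the same sign on both slides, the highest and lowest 12 of the averaged comparison, up to 4 members of each list, and the highest and lowest 5 of each other comparison. Because most IDs have no name, the rule was applied to the IDs in named tilings, passing over 988 higher and 1492 lower unnamed IDs in the averaged comparison, and the remaining named regions were added. The pairs of unnamed IDs with the largest changes were printed besides. The 21 gene lists fixed beforehand by gene symbols and products could not be matched to the IDs by name. For tacrolimus, the IDs with a probe placed once, inside an ORF of the fkb tiling, were taken instead, a rule not fixed beforehand. Only this list held at least 5 IDs, and it was tested with camera (preset correlation 0.01, and an estimated one) and with fry.

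On simulated data made from these arrays (9432 IDs, 200 of them changed), the averaged comparison recovered 16% of changes of log2 0.5, 63% of changes of log2 1 and 92% of changes of log2 2, with 3 false calls. The simulated noise was independent between IDs, with a consensus correlation of 0.143, and no normalization was run. In the data far more IDs were called, 3270 of 9527, which makes the adjusted threshold less strict. The recovered shares therefore do not give the power of the reported comparison. Alternatives were median centring, loess, the Cy3 channel alone, no background correction, Agilent's processed signals, the value table, no filter on dim IDs, the median of probes, the replicate number as a block, no block, culture as a fixed term, trend and robust moderation, and leaving out each culture. Quantiles over gene probes alone and the mean of 71 and 72 h were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No array was left out.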

Results

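RNA of *Streptomyces tsukubensis* NRRL 18488, a soil actinomycete that makes the immunosuppressant tacrolimus (FK506), was measured in cultures with added N-acetylglucosamine (GlcNAc) and in cultures without it. GlcNAc is the amino sugar unit of chitin. The medium with GlcNAc at 22.6 mM (0.5% w/v) is called NAG and the medium without it CTL. Each of 4 flask cultures, 2 per medium, was sampled at 70, 70.5, 71 and 72 h, which gave 16 arrays in 8 groups of 2. Every array compared Cy3-labelled cDNA with the same Cy5-labelled genomic DNA, and a value is the log2 ratio of the cDNA to the DNA. The labels do not say when GlcNAc was added relative to the 70 h sample. The median Cy3 spot signal of an array lay between 225 and 374, against a median local background between 46 and 63, and on the array with the fewest, 99.5% of the spots were well above background. The correlation of the log2 ratios between the replicates of a group, across features of the array, was between 0.975 and 0.994. P-values here rest on 2 cultures per group, and this number of arrays limits their precision. The array also tiles both strands of 16 named regions, and below a gene name stands for an array ID with at least 1 probe placed in the tiling of that name. For dasR, pfkA2, pfkA3, wblA and the lower of the rshA IDs only 1 of the 2 averaged probes was placed there. The first principal component held 60.3% of the variance and placed the 6 NAG arrays of 70.5, 71 and 72 h between 31.2 and 43.5, and the other arrays between -37.2 and -2.50.

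The main comparison asked which transcripts moved after 70 h in NAG and not alike in CTL: the change from 70 h in NAG minus that in CTL, averaged over 70.5, 71 and 72 h. Of the regions named for phosphofructokinases, enzymes of glycolysis, pfkA3 rose most, by log2 1.36 ± 0.14 (SE, 2 cultures per medium), or 2.57-fold, with an adjusted p of 4.41e-05. pfkA2 moved the other way, at -1.19 ± 0.18 (adjusted p 5.33e-04), and pfkA1 was 0.52 ± 0.17 higher (adjusted p 0.0353), but turned to -0.07 after loess, and missed the threshold with no culture block (0.122) and over 71 and 72 h alone (0.0585). glnR, the regulator of nitrogen assimilation, rose by 0.89 ± 0.15 (adjusted p 8.95e-04), and absA2, a response regulator of antibiotic production, by 0.94 ± 0.22 (adjusted p 0.00661). Over the whole coding strands of their tilings, which include the flanks of the genes, pfkA2 was at -0.63 ± 0.09 and absA2 at 0.50 ± 0.10. Both passed the test but were smaller. The tiling named pho, after the phosphate control system, held 3 open reading frames (ORFs). On their coding strands, ORF 2 rose by 1.11 ± 0.11, ORF 1 by 0.85 ± 0.15 and ORF 3 by 0.52 ± 0.12. In the tiling named rshA, after the RelA/SpoT family of (p)ppGpp enzymes, one ID rose by 0.80 ± 0.15 and the other fell by 0.86 ± 0.18. The tiled coding strand of that region was at -0.39 ± 0.16 and not past the test (adjusted p 0.108). Both IDs lie on this strand, so its mean checks neither of them.

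wblA, a WhiB-like regulator of development, fell the most among the named genes, by 1.53 ± 0.19 or 2.88-fold (adjusted p 1.1e-04). atrA, a TetR-family regulator of antibiotic genes, fell by 1.27 ± 0.11 or 2.41-fold (adjusted p 1.20e-05). The whole coding strand of the atrA tiling, which includes the flanks of the gene, was at -0.36 ± 0.15 and not past the test (adjusted p 0.114). dasR, the repressor of GlcNAc use genes, was at -0.29 ± 0.12 (adjusted p 0.0720), afsRS at -0.13, argR at -0.09, mmyB at 0.07, SCO1712 at 0.10 and SCO6008 at 0.21, all short of the threshold. Larger changes than those of the named genes occurred in IDs that the files pair with no name: stsu_s_0774 (-4.45 ± 0.40) and stsu_u_0442 (-4.37 ± 0.20) fell, while stsu_s_5504 (3.07 ± 0.21) and stsu_s_2836 (3.03 ± 0.39) rose.

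In all, 3270 of 9527 IDs passed the test in this comparison, 1451 higher and 1819 lower, of which 326 and 663 changed over 2-fold. The balance depended on the scaling: 44.4% of the called IDs were higher here, 40.0% after loess, 45.4% with Cy3 alone and 50.3% with median centring. It was 60.1% in the authors' values, in which 8043 IDs were tested. Of the 3270, 3241 had the same sign on both slides, which passing a test on these same slides favours. Each slide held both media, and over all IDs, called or not, the log2 changes of the slides correlated at r = 0.91. With a single NAG culture, assumed to vary like the other groups, the count was 1341 without NAG replicate 1 and 1315 without NAG replicate 2. Without NAG replicate 1, absA2 (adjusted p 0.119), pfkA1 (0.176) and both rshA IDs (0.0822 for the lower and 0.0909 for the higher) missed the threshold. Without NAG replicate 2 this held for absA2 (0.0836), pfkA1 (0.325), the IDs in pho ORFs 3 (0.0766) and 1 (0.0560) and the lower rshA ID (0.0512), which also missed it without CTL replicate 2 (0.0507). Without CTL replicate 1, dasR (0.0258) and the ID in the pho tiling outside its ORFs (0.0377, against 0.0899 with all cultures) passed it. Loess within arrays left 747 IDs, and under it pfkA3 (0.35), glnR (0.34), absA2 (0.71), pfkA2 (-0.42), wblA (-0.76), the 3 pho IDs and both rshA IDs no longer passed the test, while atrA (-0.79) did.

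**Figure D1:**
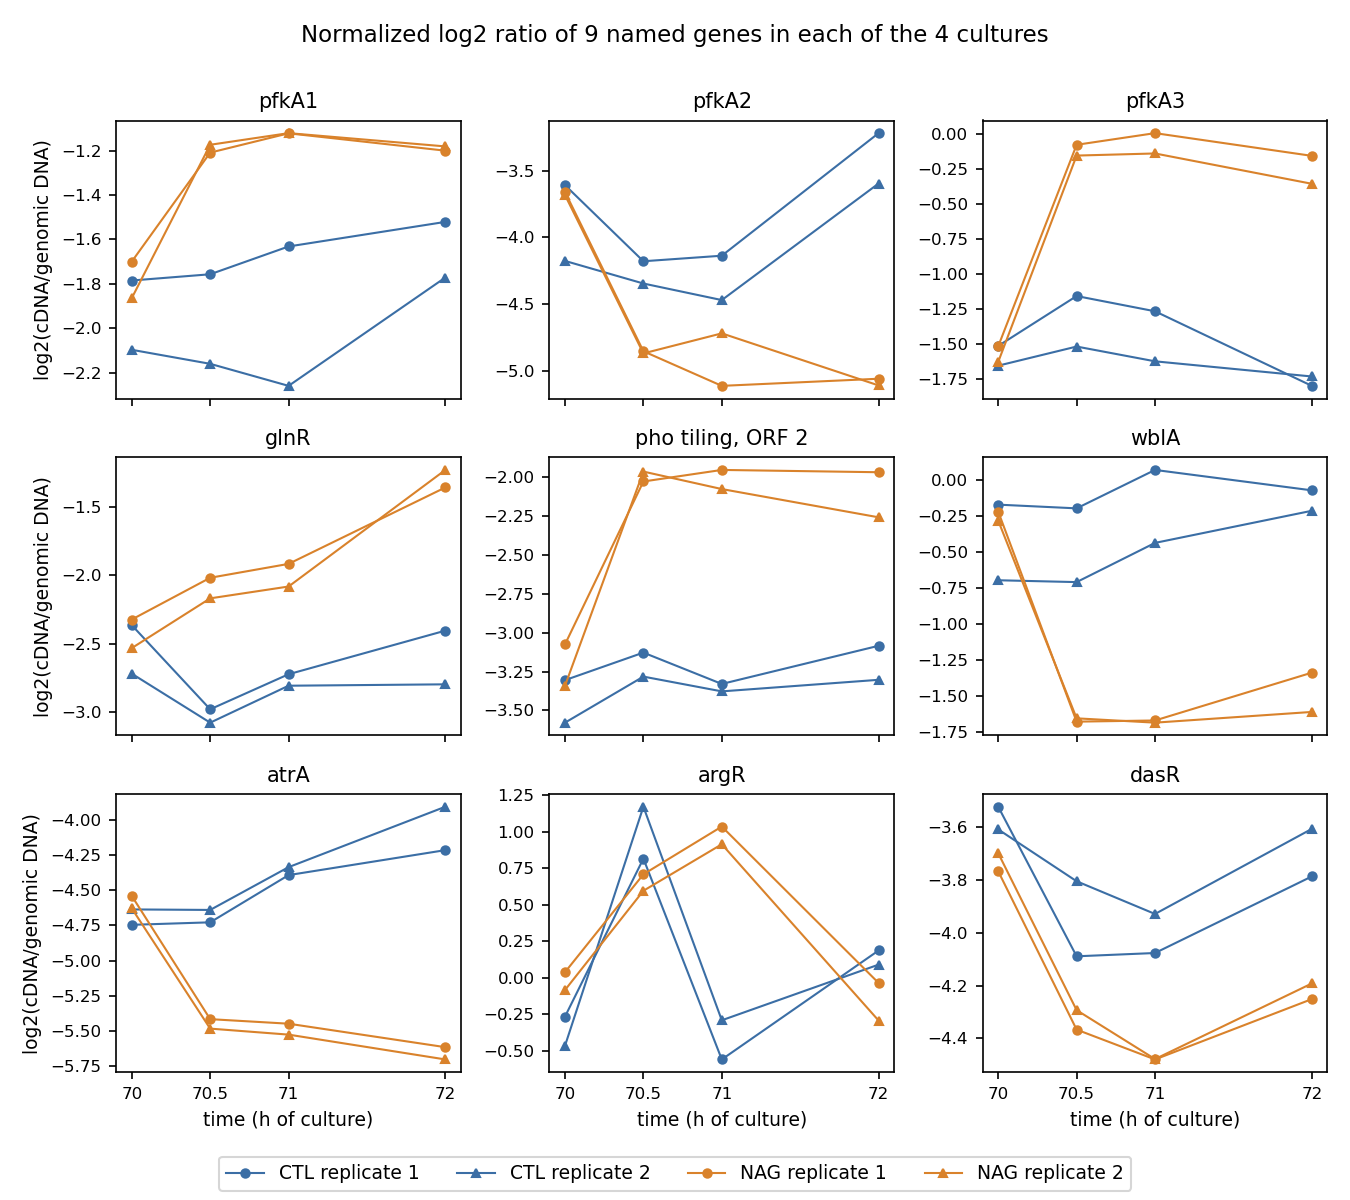
Normalized log2 ratio of cDNA to genomic DNA (vertical axis) of 9 named genes against time in h of culture, each line a culture (orange NAG, blue CTL, circles replicate 1, triangles replicate 2). Against CTL and 70 h, pfkA3 (1.36) and the ID in pho ORF 2 (0.98) rose and wblA (-1.53) and atrA (-1.27) fell on average over the later times, pfkA1 (0.52) has the opposite sign after loess (-0.07), and argR peaked at 70.5 h in CTL.

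The array tiles the region named fkb, after the genes of tacrolimus synthesis. The tacrolimus list tested here holds the 31 IDs with a probe placed once, inside an ORF of that tiling. The rule fixed beforehand, by gene symbols and products, was not applied, since no ID matched the gene table by name. By their lengths and places, 14 of the 20 complete ORFs of the tiling matched genes of the reference, against at most 2 elsewhere. By this placement ORF 9 lay at fkbA and ORF 16 at fkbC, both through their neighbours alone. The placement was not used to choose the list. None of the 31 rose and 5 fell: those in ORF 26 (-0.93 ± 0.13), ORF 11 (-0.88 ± 0.28), ORF 25 (-0.80 ± 0.16), ORF 4 (-0.69 ± 0.20) and ORF 5 (-0.52 ± 0.16), with ORFs numbered along the tiling from 1 to 32. Over the tiled probes of the coding strands, 6 of 32 ORFs fell and 0 rose: the neighbours 2 (-0.53 ± 0.14), 3 (-0.75 ± 0.17), 4 (-0.81 ± 0.20) and 5 (-0.41 ± 0.13), and the neighbours 25 (-0.77 ± 0.13) and 26 (-0.71 ± 0.11). ORFs 2 and 3 have 4 tiled probes each on the coding strand and no array ID. Of all 9527 IDs 1819 fell and 1451 rose, so the share that fell does not set the region apart. ORF 11, whose ID has 1 probe, was at -0.33 ± 0.18 over its tiled probes (adjusted p 0.220). The longest ORFs, 9 (17106 nt) and 14 (16404 nt), both incomplete in the tiling, were at 0.02 ± 0.13 and 0.10 ± 0.12.

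Adjusted over the list alone, 0 rose and 2 fell. The list as a whole did not stand apart from other IDs by camera (p 0.197, and p 0.638 with an estimated correlation), with a median of -0.12 against 0.05 for all IDs. Its median was -0.10 on one slide and -0.20 on the other, and camera with the slide as a block gave p 0.199. With fry, the list's move in one direction had a p of 0.0908 and change in either direction a p of 2.36e-04. fry asks whether members changed at all, not whether they differ from other IDs. Since 34.3% of all IDs passed the test, its small p does not set the list apart. After loess the camera p was 0.0431, the lowest over the alternatives, of which the highest was 0.393 (a culture left out). Of the 5 IDs, those in ORFs 25, 11, 5 and 4 missed the threshold without NAG replicate 1 (adjusted p 0.0640, 0.176, 0.171 and 0.197) and without NAG replicate 2 (0.0766, 0.291, 0.198 and 0.206), and that in ORF 5 without CTL replicate 2 (0.0946), so that only that in ORF 26 was left when either NAG culture was left out. After loess those in ORFs 26 (-0.33, adjusted p 0.0924), 25 (-0.15, 0.642) and 5 (-0.44, 0.140) missed the threshold and those in ORFs 11 and 4 passed it. With the slide as a block 4 of the 5 passed, and ORF 11 did not (adjusted p 0.0636). With other settings, 2 IDs of the list passed the test with no culture block, 3 with quantiles over gene probes alone, and 8 with the signals that Agilent's software had processed.

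**Figure D2:**
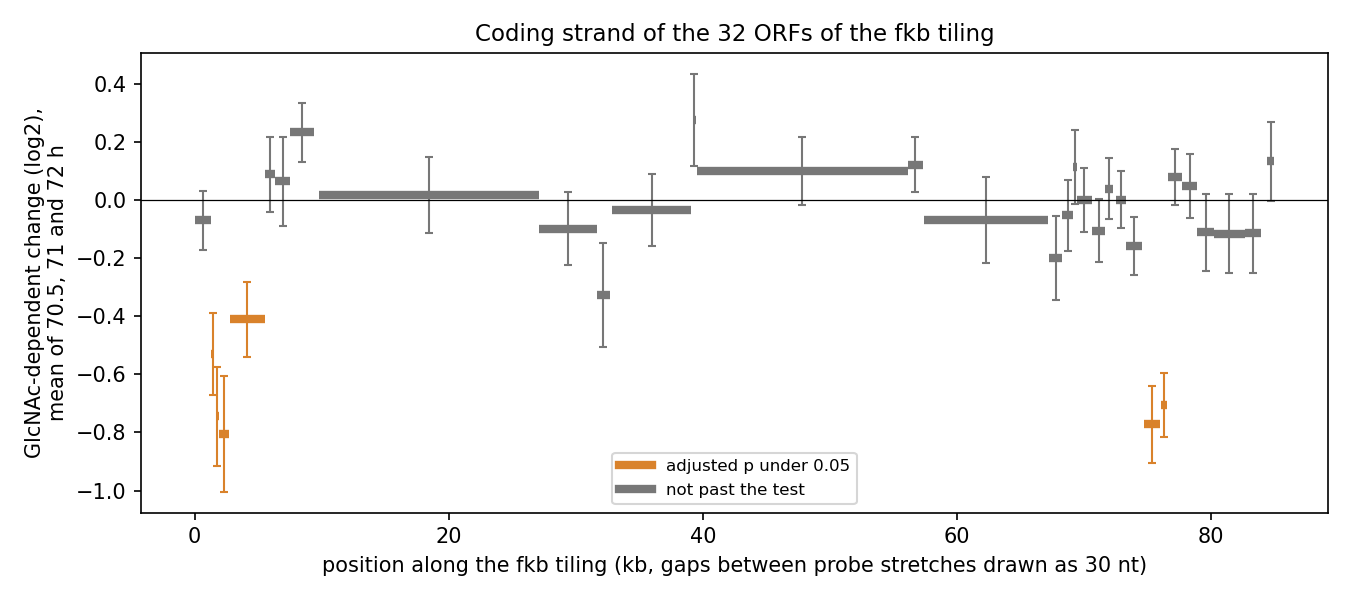
Change from 70 h in NAG minus CTL, mean of 70.5, 71 and 72 h (log2, vertical axis), of the coding strand of each of the 32 ORFs along the fkb tiling (kb, horizontal axis), each bar as long as its ORF and each whisker 1 SE. ORFs 2, 3, 4, 5, 25 and 26 (orange) had an adjusted p under 0.05, between -0.81 and -0.41.

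At 70.5 h, against 70 h and CTL, pfkA3 was already up by 1.21 ± 0.18, the ID in pho ORF 2 by 0.98 ± 0.17 and glnR by 0.82 ± 0.18, while wblA fell by 1.39 ± 0.23, atrA by 0.87 ± 0.13, pfkA2 by 0.82 ± 0.23 and the ID in fkb ORF 26 by 0.69 ± 0.15. At 71 h wblA stood at -1.67 ± 0.23, atrA at -1.23 ± 0.13 and fkb ORF 26 at -0.97 ± 0.15, and absA2 had risen by 0.90 ± 0.27. At 72 h pfkA2 stood at -1.90 ± 0.23, atrA at -1.71 ± 0.13 and the ID in fkb ORF 11 (1 probe) at -1.39 ± 0.34, and glnR at 1.19 ± 0.18, absA2 at 1.21 ± 0.27 and the higher rshA ID at 1.14 ± 0.18. Of these 6, only pfkA2 (against 70.5 and 71 h) and atrA (against 70.5 h, but not over its tiling) differed past the test from an earlier time. Over the tiled coding strands, fkb ORF 11 at 72 h (-0.52 ± 0.22, adjusted p 0.0875) and glnR at 70.5 h (0.61) did not pass the test. With flanks included, neither did pfkA2 at 70.5 h (-0.38) nor atrA at 70.5 h (-0.15) and 71 h (-0.29). For argR, the repressor of arginine synthesis, NAG minus CTL was 0.34 at 70 h (adjusted p 0.455), -0.34 at 70.5 h, 1.40 at 71 h and -0.30 at 72 h. The value at 70 h enters each change from 70 h. Against 70 h and CTL, argR went -0.68 ± 0.19 at 70.5 h, 1.06 ± 0.19 at 71 h and -0.65 ± 0.19 at 72 h, each past the test. After loess its value at 71 h was 0.14 (adjusted p 0.613), and without NAG replicate 1 or NAG replicate 2 the adjusted p there was 0.0754 or 0.0749, within a range of 0.00114 to 0.613 over all alternatives.

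By limma, 1138 IDs passed at 70.5 h (352 higher, 786 lower), 2343 at 71 h (946 and 1397) and 3761 at 72 h (1818 and 1943). In the tacrolimus list, 2, 3 and 8 IDs fell at 70.5, 71 and 72 h (1, 1 and 5 when adjusted over the list alone, and 2, 2 and 5 with the slide as a block) and 0 rose. The count at 70.5 h was 5 without NAG replicate 1, 0 without NAG replicate 2 (1321 at an unadjusted p under 0.05) and 495 without CTL replicate 2. At 71 h it was 493, 444 and 1519 in the same order, and at 72 h 1866 and 1869 without NAG replicate 1 and NAG replicate 2. Loess left 46, 326 and 1044 at the 3 times, and the Cy3 channel alone 685 at 70.5 h.

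The media were also compared directly at each time. At 70 h no named gene passed the test: pfkA3 was at 0.01 ± 0.14, wblA at 0.18 ± 0.19 and dasR at -0.17 ± 0.12. At 70.5 h pfkA3 (1.22), glnR (0.93) and pfkA1 (0.77) were higher in NAG and wblA (-1.21), atrA (-0.77) and pfkA2 (-0.60) lower. Over the tiled coding strands at 70.5 h, glnR (0.68) and the atrA tiling with its flanks (-0.25) did not pass the test. dasR was lower in NAG at 70.5, 71 and 72 h, by -0.38, -0.48 and -0.52 (adjusted p 0.0374, 0.00851 and 0.00285). It also fell in CTL after 70 h, by 0.38 at 70.5 h and 0.44 at 71 h, and was at -0.13 at 72 h (adjusted p 0.486). Over its tiled coding strand, flanks included, dasR was already at -0.38 in NAG against CTL at 70 h, not past the test (adjusted p 0.496). The averaged change of that strand after 70 h was -0.17 (adjusted p 0.321). SCO1712 was higher in NAG at 72 h, by 0.65 (adjusted p 5.54e-04), and by 0.29 over its tiled coding strand, flanks included (adjusted p 0.0215). By 72 h, 2 members of the tacrolimus list were higher in NAG and 9 lower, over all IDs and also when adjusted over the list alone.

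At 70 h limma called 0 of 9528 IDs, with 1043 at an unadjusted p under 0.05, and 1 with no culture block or from the authors' values. The differences at 70 h still correlated between the slides across IDs at r = 0.52, near the 0.55 at 70.5 h. The values of the 2 media thus differed in part alike on both slides at 70 h, and the count of 0 does not mean no difference. Among the tiled features, limma called the strand opposite to dasR at 70 h (-0.81, adjusted p 0.00866). Without CTL replicate 1 it called 372 at 70 h, and without CTL replicate 2, 1. It called 1869 IDs at 70.5 h (853 higher in NAG and 1016 lower), 2928 at 71 h (1385 and 1543) and 4361 at 72 h (2312 and 2049). 717 IDs were higher and 884 lower at all 3 later times. The differences at 70.5 and 72 h correlated across IDs at r = 0.78, and those at 70 and 72 h at r = 0.08, from different arrays of the same 4 cultures. The counts fell to 200, 1270 and 2779 at 70.5, 71 and 72 h without NAG replicate 1 and to 410, 1242 and 2814 without NAG replicate 2, and at 70.5 h to 1071 without CTL replicate 2. Loess left 355, 1078 and 2829.

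**Figure D3:**
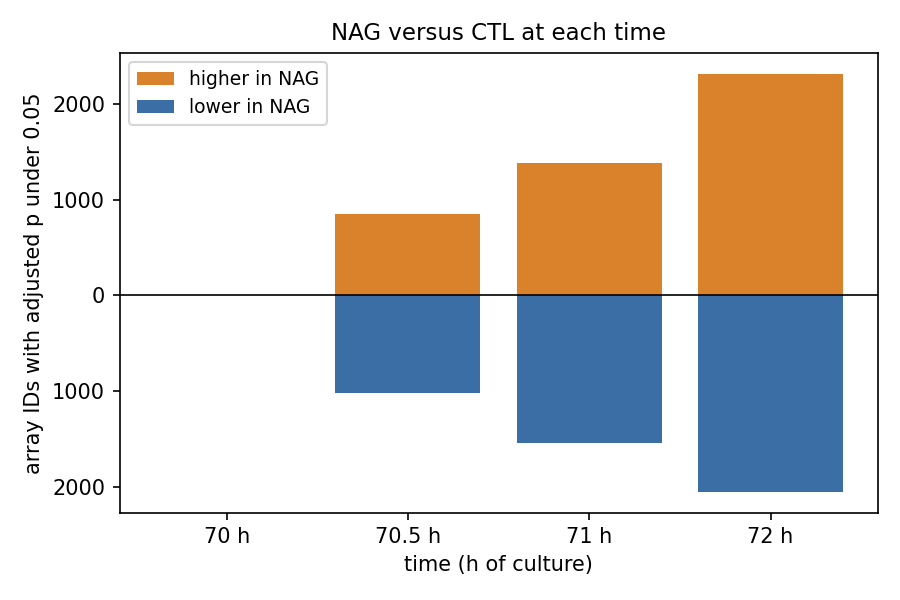
Number of array IDs with an adjusted p under 0.05 (vertical axis) in NAG versus CTL at each time in h of culture, orange above 0 for IDs higher in NAG and blue below for lower. The count was 0 at 70 h and 4361 at 72 h.

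Within one medium, the time courses show which genes moved after 70 h. In CTL, atrA rose by 0.63 ± 0.09 from 70 to 72 h, and argR rose by 1.36 at 70.5 h, stood at -0.06 against 70 h at 71 h and at 0.50 at 72 h. pfkA2, also past the test over the course, was at -0.37, -0.41 and 0.49 at 70.5, 71 and 72 h. The IDs in fkb ORFs 7, 8, 18 and 17 were lower at 72 h, by -0.69, -0.63, -0.58 and -0.56, and that in ORF 11 had its lowest value, -1.13, at 70.5 h. Each of these IDs has 1 probe. Over the tiled coding strands ORF 7 (-0.55) passed the test at 72 h and ORF 11 (-0.68) at 70.5 h, but ORFs 8 (-0.29), 18 (-0.38) and 17 (-0.32) and the atrA tiling with its flanks (0.28) did not at 72 h. In NAG, pfkA3 (1.32 at 72 h), the higher rshA ID (1.31), the ID in pho ORF 3 (1.15) and glnR (1.13) rose the most among the named genes. The IDs in fkb ORF 11 (-1.67), pfkA2 (-1.42), wblA (-1.22), fkb ORF 7 (-1.21) and 1 of the IDs in fkb ORF 16 (-1.17) fell the most. Over the tiled coding strands ORF 11 (-0.76) and ORF 7 (-0.64) fell by less. ORF 16 was at -0.20 there (adjusted p 0.186) and its other ID at -0.12 (adjusted p 0.382), neither past the test. fkb ORF 7 thus fell in both media.

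Over the course 2107 IDs moved in CTL and 4883 in NAG. In CTL, 1074 IDs differed from 70 h at 70.5 h, 849 at 71 h and 621 at 72 h, and in NAG 4079, 4883 and 4666. Of the IDs that moved in CTL at 70.5 h, 470 of the 635 higher ones were also higher in NAG than CTL at 72 h and 355 of the 439 lower ones lower, against 154 and 94.4 for independent lists. The CTL count was 606 without NAG replicate 1, 605 without NAG replicate 2, 1215 without CTL replicate 1, 1156 with no culture block and 131 after loess. The NAG count was 1787 without NAG replicate 1, 1679 without NAG replicate 2 and 2178 after loess.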

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

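The choice of which antisense and time differences to print followed the values. NAG minus CTL differed between times in several named genes, by limma tests of that difference. For argR it was 1.74 ± 0.19 higher at 71 h than at 70.5 h and stood at -1.70 ± 0.19 at 72 h against 71 h. For atrA it was -0.83 ± 0.13 at 72 h against 70.5 h. For pfkA2 it was -1.08 ± 0.23 at 72 h against 70.5 h and -1.07 ± 0.23 against 71 h. For SCO1712 it was 0.55 ± 0.14, and for the ID in fkb ORF 7 -0.86 ± 0.21, at 72 h against 71 h. Over the tiled coding strands, with flanks included for atrA, SCO1712 and pfkA2, some differences were smaller and did not pass the test. These were atrA (-0.48 ± 0.18), SCO1712 (0.24 ± 0.11) and fkb ORF 7 (-0.31 ± 0.19). Those of argR (1.71 and -1.62) and pfkA2 (-0.67 and -0.61) passed it. The 2 probes of SCO1712 had opposite signs in the averaged comparison (-0.05 and 0.25). Among all IDs, 1385 differed in it between 70.5 and 72 h (591 upward, 794 downward), and of these 1021 had the same sign at both times and a larger value at 72 h.

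The strand opposite to the coding strand was outside the comparisons above, and 6 of 49 such features passed the test in the averaged comparison. They were those of dasR (0.79 ± 0.14), pfkA1 (0.65 ± 0.14), mmyB (0.42 ± 0.09), glnR (0.36 ± 0.10), fkb ORF 18 (0.32 ± 0.09) and atrA (-0.55 ± 0.13). The coding strand stood at -0.17 for dasR, 0.52 for pfkA1, 0.19 for mmyB, 0.84 for glnR, -0.05 for fkb ORF 18 and -0.36 for atrA. The dasR feature was also lower in NAG than CTL at 70 h, by -0.81 (adjusted p 0.00866). Its 0.79 came from CTL, which fell by 0.91, 0.98 and 0.87 at 70.5, 71 and 72 h, while NAG stood at -0.21, -0.08 and -0.09 and did not pass the test, and the media did not differ past the test at these times (-0.11, 0.08 and -0.03). Tilings other than those with ORFs include flanks, where a neighbouring gene can lie on that strand.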

How the results depend on the processing

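Quantiles over gene probes alone and the mean of 71 and 72 h were tried after seeing the data; the other settings were planned. Loess gave lower counts of called IDs: 747 in the averaged comparison, 46, 326 and 1044 at 70.5, 71 and 72 h against 70 h, 355, 1078 and 2829 in NAG versus CTL at 70.5, 71 and 72 h, 131 in the CTL course and 2178 in the NAG course, and a tacrolimus list p of 0.0431. The log ratio correlated with spot brightness at r between 0.48 and 0.57, a trend that loess removes; whether that caused the loss was not tested. The Cy3 channel alone gave 685 at 70.5 h against 70 h. With no block, that count was 521, the CTL course 1156 and NAG versus CTL at 70 h 1, as in the value table (1). The causes were not tested. The value table called 2208 higher and 1463 lower, or 60.1% higher against 44.4%, and moved the median change of all IDs from 0.05 to 0.19.

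Leaving out 1 culture gave 1315 to 2950 IDs in the averaged comparison, 0 to 1310, 444 to 2313 and 1866 to 3421 at 70.5, 71 and 72 h against 70 h, 0 to 372, 200 to 2322, 1242 to 3152 and 2779 to 4610 in NAG versus CTL at 70, 70.5, 71 and 72 h, 605 to 1518 in the CTL course, 1679 to 5176 in the NAG course and a list p of 0.0819 to 0.393. With the replicate block, the averaged count was 3038, no count over all IDs moved over 1.5 times, and fkb ORF 11 missed the threshold (adjusted p 0.0636, within 7.9e-04 to 0.291 over all alternatives). In the tacrolimus list the block moved the lower IDs from 8 to 5 at 72 h against 70 h, and from 1 to 4 in NAG versus CTL at 70.5 h; the cause was not tested. No count over all IDs moved over 1.5 times in the remaining alternatives.

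Values that changed sign were argR (0.24 with median centring, 0.22 with Cy3 alone, 0.21 over 71 and 72 h, and -0.28 to 0.10 with a culture left out, the latter without CTL replicate 2), mmyB (-0.037 with loess, -0.046 without CTL replicate 2), afsRS (0.048 with loess) and pfkA1 (-0.074 with loess); the cause was not tested. Of the values of named genes, apart from left-out cultures, 291 kept direction and side of the threshold, 23 lost the call, 4 gained one (all of dasR or the ID in the pho tiling outside its ORFs) and 6 changed sign. With a culture left out these were 75, 21, 2 and 2. Of the 3270 IDs, 3118 kept their direction and 715 passed again under loess.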

Other observations

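The lower bound for the share of IDs higher in the control, and the tests of the motif in probes, of the slide, and of control levels beyond both sources were chosen after the results were seen; the other tests here were written before. The array's IDs fall into classes by their first letters, whose meaning the files do not give. All members of the class stsut that passed the test in the averaged comparison rose: 36 of 56 rose, 0 fell, and the class median was 1.01. In the class stsur, 352 of 1672 rose and 80 fell, with a median of 0.28, whereas in stsu_s 843 of 5804 rose and 1399 fell, and in stsu_u 69 of 827 rose and 186 fell. The rise of stsut held in direction under median centring, loess and the Cy3 channel alone, while loess left 5 of the 56 past the test.

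The stsut class may hold transfer RNA genes. Its IDs span 71 to 94 nt, the transfer RNAs of the reference table (assembly ASM393271v1) 71 to 93 nt, and 98.2% of its probes held the T-loop motif GTTCRA, against 5.33% of other probes. A rise of all IDs of like level was argued against, since 100% of 10000 random lists matched on mean log2 ratio had a lower median, the highest being 0.38. The class median exceeded that of all IDs by 0.96 in the reported values and by 1.03 with median centring, which has no quantile step. With median centring 36 IDs of the class rose and 0 fell, which argues against quantile scaling as the cause. The excess was 0.98 with Cy3 alone, which was also scaled by quantiles and so cannot test this. It was 0.25 with loess, which lies between the bounds set beforehand, so by those bounds the test did not decide. Loess also removes the trend of the log ratio with brightness, and whether that lowered the excess was not tested. Whether a change in transfer RNA level or in its recovery raised the class was not tested.

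The CTL cultures moved at 70.5 h along the direction of the later GlcNAc difference. Across IDs, the control change at 70.5 h on one slide correlated with NAG minus CTL at 72 h on the other at r = 0.52 and 0.36, which argues against the slide as the cause. With median centring the lower of these was 0.37, which argues against quantile scaling. Neither setting removes the trend of the log ratio with brightness. Loess, which does, lowered the count of the CTL course from 2107 to 131 IDs. The correlations were not computed after loess, so a part of that trend in the move was not tested. The move faded later: for the control change at 71 h the correlations were 0.21 and 0.21, and at 72 h -0.11 and -0.20. RNA of a GlcNAc culture in the control samples, as the whole cause, would place control levels between CTL at 70 h and that culture. Of 370 IDs changed in the control at 70.5 h (adjusted p under 0.01, which allows 3.7 false calls), 31 lay outside the interval from CTL at 70 h to NAG at 70.5 h. Both tests behind this count share the CTL arrays of 70.5 h, whose noise can place IDs outside, which the 3.7 leaves out. RNA of NAG at 71 or 72 h was not covered either, so the count does not decide. Of IDs over 2-fold higher in NAG at 72 h, 86.1% and 84.8% were higher in the control on the other slide. Both lie under the 90% set beforehand, which by that bound argues against such RNA. The bound was lowered to 75% only after the result was seen, because it ignored noise (SD 0.34 between the CTL replicates at 70.5 h), and by the later bound these shares do not exclude a part from such RNA. Of IDs over 2-fold lower in NAG, for which no bound had been set, 79.3% and 70.5% were lower in the control, and the latter lies under the later bound too. With single arrays the noise keeps these shares from deciding, so such RNA stays open as a part or the whole of the cause. A response of the CTL cultures to handling or to their own state may also underlie the move and was not tested.

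A hypothesis was that neighbouring genes responded together, with the number of an ID in the class stsu_s taken as its place. Of lower IDs, 42.5% were followed by another lower ID, against 24.1% on average and at most 28.3% in 10000 permutations, and of higher IDs 30.9% were followed by a higher one, against 14.5% and at most 19.7%. The longest runs were 8 lower and 7 higher IDs, and the changes of neighbours correlated across IDs at r = 0.37. Responses of operons or clusters would give this. The files do not state that the numbers follow the genome, but they ran in order along the pho tiling and nearly so along the fkb tiling. Consecutive IDs can also lie in the same ORF, as stsu_s_4447 and stsu_s_4448 do in fkb ORF 16. Such pairs would add to these shares, and their part was not tested.

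The 4 cultures can be split into pairs in 3 ways, too few for a share under 0.05. The real split called 3270 IDs and the highest other split 0, and it was 1 of 3 to call as many. Each other split puts a NAG and a CTL culture into the same group. The difference between the media then adds to the spread, so few calls were to be had there and no conclusion is drawn.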
